A study of Caenorhabditis elegans with 2 samples.

How the data were processed

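Chromatin immunoprecipitation with sequencing was carried out on whole Caenorhabditis elegans larvae of a transgenic strain that expresses T20F7.1 fused at its C terminus to TY1, EGFP and FLAG tags. Per the labels, an anti-GFP antibody was used, the animals were L4 larvae of mixed sex aged 48 hours, and cultures had been synchronised by starving hatched larvae after bleaching. The transgene also carries a wild-type copy of unc-119, the rescue marker of the strain. There was 1 group with 2 biological replicates, which the labels list as separate biosamples. A control alignment is named as a parent of the lists in the text deposited beside them, but no control, input or untagged immunoprecipitation was analysed here.

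The authors deposited 4 peak lists on assembly ce11, which is the WBcel235 sequence. 2 lists hold the candidate regions of the single replicates and 1 list the candidate regions of the pooled replicates, with 30000 regions each. The remaining list holds the 2586 peaks the authors kept after the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates. The signal value of each region is the height that the authors' peak caller gave, per the deposited lists, and it is used here only to rank and describe regions. The −log10 q-value in the deposited lists is also the authors', and the p-value column holds no values. The summit position is the region start plus the offset in the deposited lists. The peak caller, the aligner, their versions and the scale of the signal values are not given in the sources used here. Read depth is unknown, because the lists hold no read counts, so intervals given with shares cover the sampling of peaks or genes and not sequencing depth.

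Genes were taken from Ensembl release 115 on the 6 nuclear chromosomes, with 19973 protein-coding genes. Chromosome names and lengths of the lists were checked against the WBcel235 sequence. A promoter peak has its summit from 500 bp upstream to 100 bp downstream of an annotated gene start, and 1 summit can lie in the windows of several genes. Other summits were placed, in order of priority, in 5′ UTR, coding exon, 3′ UTR, intron, non-coding gene or intergenic sequence. Chance levels came from circular shifts of all summits along their chromosomes, 1000 for locations and 100 for the replicate overlap. The smallest p they allow is 0.001 and 0.0099. Replicate overlap was the share of the 2586 strongest regions of replicate 1 with a summit within 100 bp of a summit among the 2586 strongest regions of replicate 2, tested one-sided. Rank correlation across peaks was Spearman's, with an interval from 1000 bootstrap draws and no p, since peaks are not independent replicates.

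Gene lists, 27 in number, were written by gene name before the data were examined, and each was compared with all other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over the lists at 0.05. Odds ratios carry a 95% interval with 0.5 added to each cell. The same test compared X with autosomal genes, and genes in the middle of the autosomes (25 to 75% of the length) with those nearer the ends. Non-coding biotypes with at least 20 genes were tested one-sided for summits within 250 bp. Median signal values were compared by two-sided permutation tests with 100000 resamples. For sequence words, the presence of each of 2080 6-mers (a word and its reverse complement together) within 50 bp of the summit was compared with its presence 300 to 400 bp away on both sides, by an exact binomial test on the peaks where they differed. The summit window enters once for each side, so those p-values are too small. Shares carry 95% Wilson intervals. All p-values are across peaks or genes within 1 group of 2 replicates and say nothing about variation between animals.

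Genes named in the text follow a rule fixed before the data were examined. It takes T20F7.1 and unc-119, the genes nearest the 10 strongest promoter peaks, the 3 strongest members of each list past the threshold, the strongest member of each other list, and the 10 6-mers with the smallest p. The result for 1 chemoreceptor gene chosen by this rule was left out because it needs an item withheld for evaluation. Longer words were looked at afterwards and are reported with the closing observations. The alternatives tried were other distances, windows and overlap criteria, stricter peaks, either replicate alone, transcript starts, the nearest gene alone, other backgrounds and other sequence controls.

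The computations were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The tests were tested on simulated data with the real genes. With summits placed at random in 40 runs, 0 promoter shares and 3 of 1080 list tests were called. A planted promoter share of 46.7% was recovered as 46.6% over 20 runs, in all of which the planted ribosomal protein list was called. With 1600 planted shared summits, 1607 shared summits were counted, chance matches included.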

Results

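T20F7.1 encodes a protein that the reference annotation describes as containing a C2H2-type domain, a zinc finger fold common in DNA-binding proteins. Its genomic sites in L4 larvae were measured by immunoprecipitation of the tagged protein from whole animals, in 2 biological replicates. The data are 30000 candidate regions for each replicate, 30000 for the pooled replicates and 2586 peaks that the authors retained by IDR. The retained peaks were the 2586 pooled regions with the highest signal values, and 27414 pooled candidates lay outside them. Their signal values had a minimum of 95.6 and a median of 144, and the strongest peak was 63.4 times the weakest. Of these peaks, 1169 (45.2%) had a −log10 q of at least 2 in the authors' deposited list. All coordinates are those of ce11.

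The first comparison was between the replicates. The strongest sites were the same: the promoter peaks of cmtr-1 (an mRNA cap methyltransferase), rps-28 (a small ribosomal subunit protein), timm-23 (mitochondrial inner membrane translocase), luc-7L3, dld-1 (dihydrolipoyl dehydrogenase) and F52C12.2 held ranks 1 to 6 in that order in both replicates. Among the 2586 strongest regions of replicate 1, 1688 (65.3%, 95% interval 63.4 to 67.1) had a partner among the 2586 strongest of replicate 2. Circular shifts gave a mean of 0.529% and a maximum of 0.851% (permutation p = 0.0099, one-sided, the smallest possible). With all candidates of replicate 2 the share was 87.4%. Both replicates had a partner in their strongest lists for 513 of 518 peaks in the strongest 20% of IDR peaks and for 21 of 518 in the weakest 20%, where peaks lie close to the limit of those lists.

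Signal values at 2442 IDR peaks matched in both replicates had a Spearman correlation of 0.743 (0.718 to 0.767) across peaks. From the weakest to the strongest 20% of peaks it was -0.707, -0.665, -0.516, 0.259 and 0.957. These groups were formed on the pooled signal, to which both replicates contribute. Such grouping by itself lowers the correlation within narrow groups and can make it negative. The negative values therefore do not show that the replicates disagree at weak peaks. The log2 ratio of replicate 2 to replicate 1 had a median of 0.03, quartiles of -0.21 and 0.29, and an SD of 0.47. The peak at cmtr-1, at chromosome II 15025617 to 15026292, had signal values of 3242 and 2826 in replicates 1 and 2. That of rps-28, at chromosome IV 1658915 to 1659574, had 2197 and 2159. Pearson's r of log2 values was 0.904, and the rank correlation in the stronger 50% of peaks was 0.851.

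**Figure D1:**
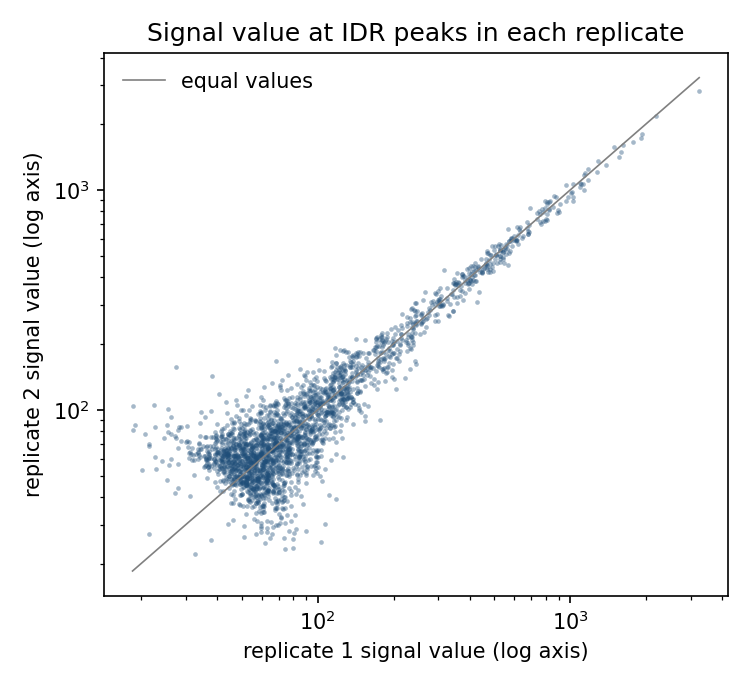
Signal value of the 2442 IDR peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both log axes in the authors' units. Each point is a peak and the line marks equal values; strong peaks lie close to the line and the spread is wider among weak ones.

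The second comparison asked where in the genome the peaks lay. Promoters of protein-coding genes held 1188 of the 2586 summits (45.9%), 4.13 times the circular-shift mean of 11.1%. No shift exceeded 13.5% (permutation p = 0.001, one-sided, the smallest possible). Coding exons held 2.59% of summits against 22.6% in the shifts, and introns 19.1% against 32.9%. Intergenic sequence held 24.7% against 25.8%, a difference within the shifts (adjusted permutation p = 0.234), but it was called lower in the stronger 50% of peaks (22.4%) and with the wide promoter window (18.9%), and higher with the narrow window (36.9%). The 3′ UTR share of 3.71% was above the shift mean of 2.82% (adjusted permutation p = 0.014), but in the stronger 50% of peaks it was 1.93% and no longer above, and without replicate 2 it was 3.44% and the call was lost. Non-coding genes held 2.51% against 3.65% (adjusted permutation p = 0.0105), a call lost in the stronger 50% of peaks and with the narrow window. This class counts pseudogenes and leaves out sequence inside promoter windows or protein-coding genes, so it does not describe RNA genes as such. The 5′ UTRs held 1.51% against 1.05% (adjusted permutation p = 0.0536), which was called higher without replicate 2 (1.59%) and with the narrow window (2.09%).

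**Figure D2:**
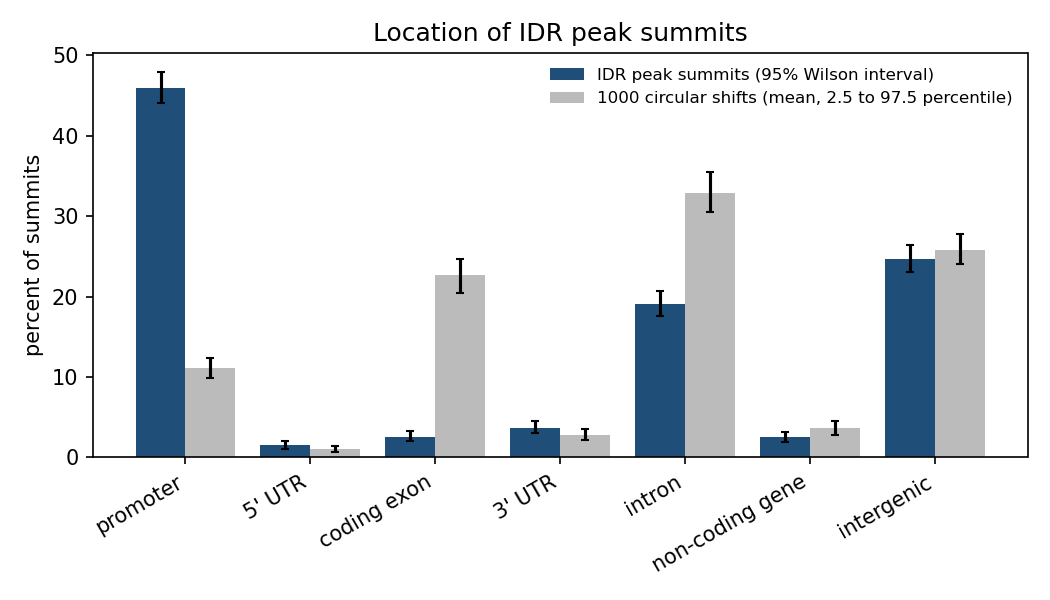
Percent of the 2586 IDR peak summits in each class of location (dark bars, 95% Wilson intervals) and in 1000 circular shifts (grey bars, mean with the range of the middle 95%). Promoters stand at 45.9% against 11.1%, and coding exons at 2.59% against 22.6%.

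Promoter summits lay at a median of -173 bp from the gene start (quartiles -285 and -80 bp, negative upstream), and 92.3% were upstream of it. Stronger peaks were more often at promoters: the share was 30.9% (27.1 to 35.0) in the weakest 20% by signal, then 35.4%, 40.2%, 50.3% and 72.9% (68.9 to 76.6) in the strongest. The median signal value was 174 at the 1188 promoter peaks and 129 at the 1398 others (two-sided permutation p = 1e-05, the smallest possible). The 10 strongest promoter peaks were those of cmtr-1, rps-28, timm-23, luc-7L3, dld-1, F52C12.2, mrps-7, pri-2 (a DNA primase subunit), T23F6.3 and F02C12.3, the last with a signal value of 2669. The summits, with chromosome, position and distance upstream of the gene start, were cmtr-1 (II, 15025976, 138 bp), rps-28 (IV, 1659267, 424 bp), timm-23 (I, 11578398, 243 bp), luc-7L3 (II, 98157, 130 bp), dld-1 (IV, 14464263, 254 bp), F52C12.2 (IV, 1953301, 278 bp), mrps-7 (IV, 14767901, 171 bp), pri-2 (I, 12532357, 222 bp), T23F6.3 (IV, 12724846, 86 bp) and F02C12.3 (X, 13396752, 221 bp). The summit at luc-7L3 also lies 247 bp upstream of sftb-6, a splicing factor gene on the other strand. Those of mrps-7, pri-2 and T23F6.3 likewise lie in the promoter window of a second gene.

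The third comparison asked which genes had promoter peaks. In all, 1460 of 19973 protein-coding genes (7.31%) had one. Genes of the protein synthesis, energy and protein turnover machinery had them more often than other genes, and genes of cuticle, chemosensation and neuropeptide signalling less often. Of the 27 lists, 11 had promoter peaks more often, 6 less often and 10 gave no call. Against circular shifts of the summits in place of other genes, 13 lists were higher and 1, the chemoreceptors, lower. Nuclear hormone receptors and detoxification enzymes were then called higher, and the other 5 lower calls were lost.

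Ribosomal protein genes had promoter peaks at 47 of 82 (57.3%) against 1413 of 19891 other genes (odds ratio 17.6, 11.3 to 27.1, adjusted Fisher exact p = 3.88e-31). Their strongest peaks were at rps-28 (signal value 4338), rpl-3 (2300) and rpl-28 (2185), the last shared with mrpl-49 on the other strand. With the narrow window of 250 bp upstream to 50 bp downstream the ribosomal protein odds ratio was 3.28. It was then below splicing factors (6.80), the mitochondrial ribosome (6.32), the respiratory chain (5.19) and heat shock proteins (4.93). Autophagy (4.59), translation (3.89), proteasome (3.77) and vacuolar ATPase genes (3.51) also stood above it, and intestine (2.32) and cell cycle genes (1.94) below it. With each summit given to the nearest start alone the ribosomal protein odds ratio was 9.02, and that of proteasome genes fell to 5.19. Respiratory chain genes had 21 of 56 (odds ratio 7.70, 4.54 to 13.3), led by asb-2 (1769), cox-10 (1590) and cox-6C (1479). Of the mitochondrial ribosome genes 19 of 70 had a peak (4.77, 2.87 to 8.19), with mrps-7 (3086), mrpl-49 (2185) and mrps-25 (1997) strongest. Translation factors and tRNA synthetases had 18 of 71 (4.35, 2.60 to 7.53), led by eif-3.E (1970), eif-3.B (1564) and eef-1A.1 (1253), an elongation factor gene.

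Splicing factor genes had promoter peaks at 22 of 62 (odds ratio 7.07, 4.25 to 12.0). The strongest were sftb-6 (3618), prp-8 (2278), a core spliceosome component, and lsm-5 (1092). Proteasome genes had 13 of 33 (8.31, 4.22 to 16.8), with rpt-2 (2484), pas-4 (1695) and pbs-2 (1216). Heat shock protein genes had 13 of 53 (4.15, 2.29 to 7.89), with dnj-22 (1646), dnj-10 (1009) and hsp-110 (683). Vacuolar ATPase genes, whose products acidify organelles, had 8 of 21 (7.84, 3.39 to 18.9), with vha-8 (345), vha-1 (269) and vha-12 (246). Autophagy genes had 7 of 28 (4.24, 1.93 to 10.2), with lgg-2 (303), atg-16.1 (214) and epg-8 (207). Cell cycle genes had 13 of 83 (2.37, 1.36 to 4.38, adjusted Fisher exact p = 0.0159), with cdc-48.1 (2144) and the cyclin gene cyb-1 and orc-5, which share 1 peak (1798).

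The peaks of cox-10, cox-6C, mrps-25, eef-1A.1, rpt-2, pas-4, pbs-2, dnj-22, hsp-110, vha-8 and vha-1 each lie in the window of a second gene too, such as rfc-4 beside eef-1A.1, aps-1 beside rpt-2 and rpn-3 beside hsp-110, and cannot be given to either gene alone.

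Intestine genes had 12 of 81 (odds ratio 2.22, 1.25 to 4.19, adjusted Fisher exact p = 0.0261), all of them weak peaks: ile-1 (140), cpr-4 (139) and then lys-8 were the strongest. The stronger 50% of peaks held none of these 12, and the call was also lost with either replicate alone. Calls of the vacuolar ATPase, cell cycle and autophagy lists were lost under 1 or more alternatives as well, whereas those of the other 7 lists were kept under all.

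Cuticle collagen genes had 0 of 176, which allows a share of up to 1.70% (adjusted Fisher exact p = 8.70e-06). Chemoreceptor genes had 5 of 1318 (odds ratio 0.0450, 0.0214 to 0.115, adjusted Fisher exact p = 5.92e-36). The peak at srd-4 (726) is shared with usip-1, and srh-70 (204) has its own. Neuropeptide and insulin genes had 1 of 145, at nlp-4 (156), in a window shared with exos-3. Lysozyme, lectin and antimicrobial peptide genes had 5 of 345 (0.184, 0.0867 to 0.469), with spp-5 (151), lys-8 and spp-3 (131) strongest. F-box and MATH-BTB genes had 12 of 433 (0.356, 0.211 to 0.652), with bath-41 (793), fbxc-54 (526) and fbxb-85 (286), each in a window shared with another gene. Hypodermis and seam genes had 1 of 95, at wrt-3 (190), with an interval that reached 1 (0.134, 0.0399 to 1.01, adjusted Fisher exact p = 0.0256), and this call was lost under 5 alternatives.

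No call was made for histone genes (3 of 82, his-37 at 1042 the strongest), nuclear hormone receptors (15 of 274, nhr-47 at 427, shared with dnj-19), homeobox factors (2 of 93, ceh-38 at 428, shared with malt-1), neuronal synapse genes (2 of 47, ric-19 at 1298, shared with pmlr-1), muscle genes (2 of 57, act-2 at 139), pharynx genes (5 of 105, pqn-41 at 1527, shared with B0524.6), germline genes (2 of 69, syp-2 at 1025, shared with cox-16), sperm genes (2 of 87, spe-54 at 125), detoxification enzymes (11 of 188, ugt-62 at 147) and heterochronic genes (2 of 15, lin-66 at 282). Under single alternatives 4 of these lists were called lower: homeobox factors without replicate 2 or with transcript starts, sperm genes in the stronger 50% of peaks or without replicate 1, detoxification enzymes in the stronger 50% of peaks or among genes with a candidate region, and nuclear hormone receptors with the narrow window. Whole animals were used, so the tissue lists describe which genes had a peak and assign no binding to a tissue. Membership of every list rests on the gene name alone, so a single named member, such as ile-1 or pqn-41, may not belong to the tissue named.

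**Figure D3:**
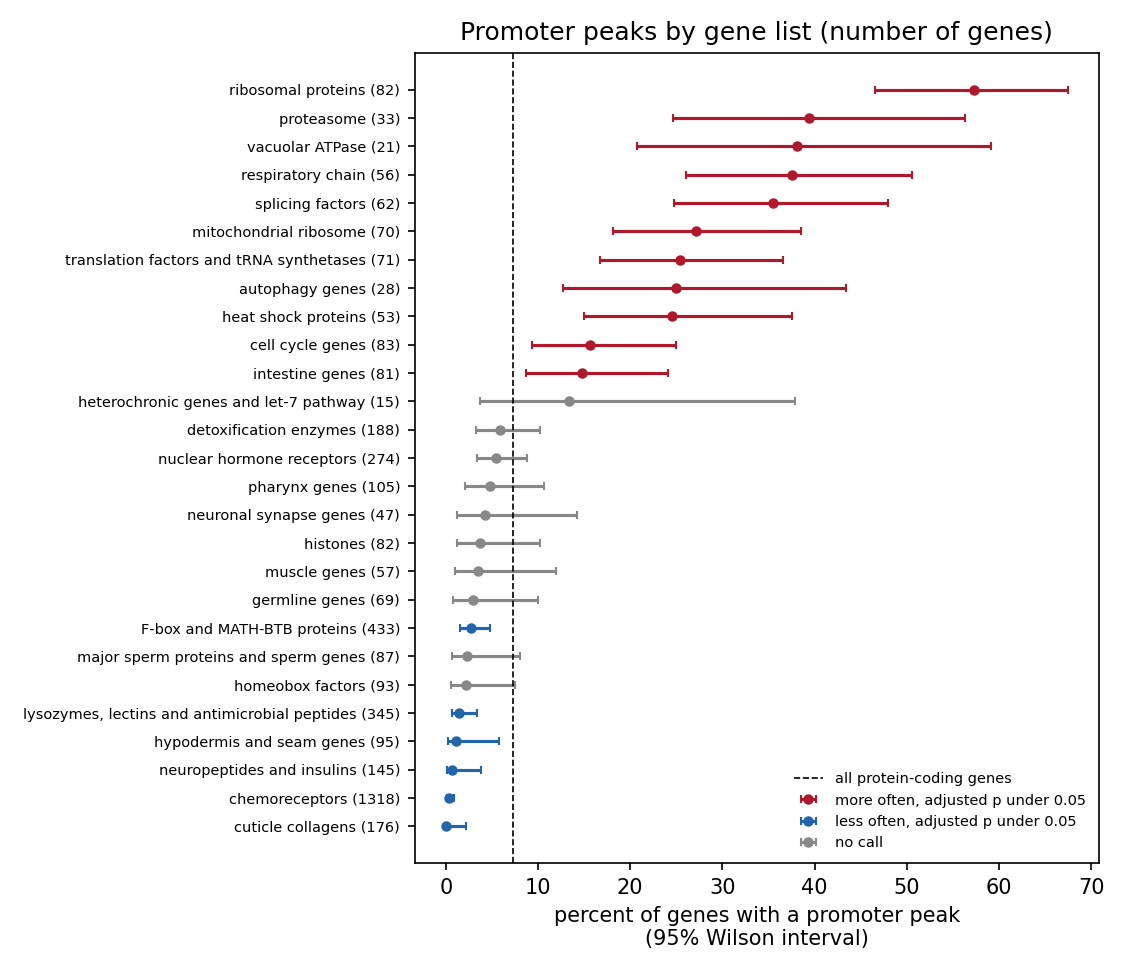
Percent of the genes of each of the 27 lists with a promoter peak (x axis, 95% Wilson intervals; number of genes in brackets), with the share of all protein-coding genes, 7.31%, as a dashed line. Ribosomal protein genes stand at 57.3% and chemoreceptor genes at 0.379%.

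The fourth comparison was between chromosomes. Genes on X had a promoter peak less often than autosomal genes, 158 of 2731 (5.79%) against 1302 of 17242 (7.55%), with an odds ratio of 0.752 (0.636 to 0.893, adjusted Fisher exact p = 0.000877). Autosome V was as low, at 5.55% (4.95 to 6.22), and chromosomes I and III stood highest, at 9.83% and 9.55%. A low share of genes was therefore not particular to X. Peaks of all locations were denser on X (25.3 per Mb) than on V (20.3 per Mb), and the other autosomes held 24.0 to 31.8 per Mb. Autosomal genes in the chromosome centres had one more often than those nearer the ends, 10.6% of 9597 against 3.70% of 7645 (odds ratio 3.09, 2.70 to 3.53, adjusted Fisher exact p = 1.65e-69). Among the 5254 genes with any pooled candidate region in the promoter window, a background chosen after seeing the data, the central odds ratio was 0.966 (0.825 to 1.13) and the X odds ratio 0.608 (0.506 to 0.734). Chromosome V was not compared by itself in that background.

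The fifth comparison concerned non-coding genes. Transfer RNA genes lay near summits more often than chance, with 143 of 612 (23.4%, 20.2 to 26.9) within 250 bp of a summit against 1.46% in circular shifts (permutation p = 0.001, one-sided, the smallest possible). Small nucleolar RNA genes had 61 of 346 (17.6%), 10.8 times the shift mean, and small nuclear RNA genes 14 of 129 (10.9%), 7.30 times the shift mean. In all, 7 of the 10 biotypes passed the threshold. Those not yet named were ncRNA (5.15%, 3.16 times the shift mean), microRNA (4.98%, 3.34 times), antisense RNA (9%, 2.61 times) and lincRNA (8.25%, 2.06 times) genes. Circular shifts do not remove the excess of summits at protein-coding promoters, which was itself 4.13-fold. Nearness to such promoters was examined for tRNA genes alone, so it stays open as a source of the other calls. Pseudogenes (1.13%) and piRNA genes (0.325%) lay below their shift means of 4.29% and 1.24%, and 0 of 20 rRNA genes were near a summit. The antisense RNA and lincRNA calls were lost at 100 bp and also without replicate 2 (adjusted permutation p = 0.0828 for each), and the lincRNA call in the stronger 50% of peaks. tRNA genes with an identical copy elsewhere lay near a summit more often (122 of 469) than those of unique sequence (21 of 143).

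At the loci of the transgene, T20F7.1 (X, 16872912 to 16878351, plus strand) and unc-119 (III, 10902641 to 10908935, plus strand), there was no IDR peak within 20 kb. The genome-wide density gives 1.17 and 1.19 peaks in intervals of this size, so these counts alone do not differ from it (upper Poisson bound 3.69).

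The last comparison was of the sequence at summits with that of flanks of the same peaks. Of 2080 6-mers, 578 were more frequent within 50 bp of the summit and 500 less frequent. With each summit window entered once, against a single flank, 382 were more frequent. ACGCGC occurred at 8.97% of summits and in 1.47% of flanks (6.11-fold), ACGCAG at 9.78% and 1.88% (5.22-fold) and GACGCA at 9.16% and 2.09% (4.39-fold). ACACTC was found at 11.5% and 2.94%, CGTCTC at 10.4% and 2.96%, AGAGAC at 12.0% and 4.31%, ACACGC at 7.35% and 1.80%, and AGCGCG at 6.54% and 1.37%. CACACA and ACACAC were also higher, by 2.65-fold and 2.89-fold. The adjusted exact binomial p was 3.12e-68 for ACGCGC, the smallest, and 5.46e-41 for ACACAC, the largest of these 10. Both are too small because each summit window enters once for each flank, and against a single flank the adjusted exact p of ACGCGC was 1.36e-31. GC content was 39.5% at summits and 35.8% in flanks, and against windows shuffled to keep their dinucleotides 240 6-mers were called, of which 175 were among the 578. Against these the ratios were smaller: 2.00 for ACGCGC, 2.69 for ACGCAG, 2.24 for GACGCA and 1.69 for AGCGCG.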

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

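Signal appeared among pooled candidate regions outside the IDR list, whose own locations were not among the planned comparisons. The 2586 regions ranked 2587 to 5172, just below the IDR list, had summits in promoter windows at 23.2% (21.6 to 24.8), which made them stand out, since the upper end of the middle 95% of 200 circular shifts was 12.5%. In ranks 15001 to 30000 the share was 13% (12.5 to 13.5), against an upper end of 11.7% in the shifts. No sample without the tag was analysed here, so chance placement was the only comparison available.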

How the results depend on the processing

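Promoter share, X chromosome genes, promoter signal and replicate overlap kept direction and side of the threshold under all alternatives tried. The signal ratio and the loci had no test. The median log2 ratio stayed between 0.0220 and 0.0318, and the loci stayed without an IDR peak. With either replicate alone, the promoter share was at most 46.2%, enriched lists 10 and 10, and higher 6-mers 563 and 545. The rank correlation rose to 0.904 as Pearson's r, 0.851 in the stronger 50% of peaks and 0.802 at 50 bp. Higher 6-mers numbered 240 against shuffled windows, 363 outside promoters and 382 against a single flank, an alternative added after seeing the data. The central odds ratio turned to 0.966 among genes with a candidate region, also added afterwards; the cause was not tested.

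In the stronger 50% of peaks, the 3′ UTR share fell to 1.93%, below its shift mean. The intestine list fell there to an odds ratio of 0, since its strongest peak (140) lay below the median signal value (144). With the narrow promoter window, promoter summits fell from 45.9% to 30.2%. Summits that leave this class pass to the others by definition. Intergenic summits rose to 36.9%, above their shift mean, and the odds ratios of uncalled lists turned for pharynx (1.05), detoxification (1.18) and heterochronic genes (0). Heterochronic genes turned to 0.904 without replicate 2, against 1.94 without replicate 1, and detoxification genes to 1.00 with the nearest start. Circular shifts do not remove the excess of summits at promoters in general, so by construction 11 lists turned to a ratio over 1: histones 2.49, nuclear hormone receptors 4.22, homeobox 1.32, synapse 2.76, muscle 2.40, pharynx 3.24, germline 1.86, sperm 1.49, detoxification 4.30, lysozymes 1.02 and F-box 1.74. Among genes with a candidate region, histones turned to 1.56 and synapse genes to 1.04. The causes of the other changes were not tested. No paired analysis was possible because there was 1 group. Read depth is unknown, so what it limits could not be measured.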

Other observations

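The tests of neighbouring genes, strong transcription, promoter peaks in general and unique tRNA genes were chosen only after the results they bear on were seen, as were all longer sequence words and the spacing of 2 of them.

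Some longer words differed between strong and weak peaks. All 32896 words of the length of ACACTCCG were compared, and 1368 were more frequent at summits than in flanks. The words named here were picked after that comparison, by no rule fixed beforehand. ACACTCCG lay within 50 bp of 97 summits (3.75% against 0.0773% in flanks), and the median signal value of those peaks was 938 against 141 for the rest (permutation p = 1e-05). It occurred at 17.2% (14.2 to 20.7) of the strongest 20% of peaks and at none of the weakest 20%. Of its copies in promoter windows 96 (37.5%, 31.8 to 43.6) lay at a summit, while 1.06% of all promoter positions did. This share ranked 2 among 32057 words with at least 50 promoter copies. ACACTCCG was picked for its excess at these same summits, so a high rank follows in part from the choice. The permutation p for signal takes no account of that choice either. Of the 1384 copies of ACACTCCG in the whole genome 103 lay at a summit. The most frequent sequence around it was ACGACACTCCG. GTTGTTTA was also more frequent at strong peaks, at 15.7% of the strongest 20% and 0.772% of the weakest, but its excess over flanks was 7.36-fold against 48.5-fold for ACACTCCG, and 12.5% (10.2 to 15.3) of its promoter copies lay at a summit. In the whole genome 107 of its 4546 copies did. AGACGCAG occurred at 4.87% of summits, more than any other word named here. It was spread more evenly than ACACTCCG or GTTGTTTA, at 1.74% of the weakest 20% of peaks, 9.09% of the second strongest 20% and 6.96% of the strongest. The median signal of peaks with AGACGCAG was 1.44 times that of the rest. TCTTATCA, which holds the GATA sequence, ran the other way, at 6.76% (4.90 to 9.25) of the weakest 20% and 0.967% (0.414 to 2.24) of the strongest.

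No candidate region of the pooled list, of 30000, lay within 20 kb of T20F7.1 or of unc-119, where the genome density gives 13.6 and 13.9. The stretch without candidates was 82.4 kb at T20F7.1 and 137 kb at unc-119, against a median of 1382 bp between neighbouring candidates, and these ranked 102 and 37 among 29994 stretches. In the replicate lists it was 84.6 and 81.4 kb at T20F7.1, and 136 and 88.7 kb at unc-119. The strain carries extra copies of both genes, and the control alignment was not analysed here.

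The excess of promoter peaks at the 11 lists called more often, a set that includes the intestine genes, was set against 3 technical explanations. Counting 1 summit for several genes does not account for all of it, since all 11 lists kept their call with the nearest start alone, but the ribosomal protein odds ratio fell there from 17.6 to 9.02. A weak enrichment equal at all promoters would leave no difference among genes that have a candidate region. There the ribosomal protein odds ratio was 31.5 (10.7 to 74.6), which argues against that form for this list. The IDR peaks are the strongest pooled candidates, so an enrichment larger at some promoters could give the same difference. The test cannot exclude that form. In that background 8 of the 11 lists kept their call. Vacuolar ATPase (1.89), autophagy (3.04) and intestine genes (1.16) lost theirs, so even an equal enrichment stays open for them. Strong transcription stays open: the upper bound of the muscle share was 11.9%, below the ribosomal lower bound of 46.5%, but no expression was measured here and both shares were known beforehand, and chromatin open in all cells was not tested for want of an untagged sample.

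For ACACTCCG, base composition is argued against by shuffled summit windows, 0.159% (0.117 to 0.215) of which held the word, against 3.75% unshuffled. The word was picked for its excess in these same windows, so this is no independent test. Copies of 1 repeat are argued against by the 60 bp around it, where 2 of 97 windows (2.06%) had a partner of 80% identity or more. A general mark of promoter peaks is argued against, since 91 of 1188 promoter peaks held the word and among promoter peaks the median signal was 6.04 times higher with it (991 against 164, permutation p = 1e-05), although nearly all peaks with the word lay at promoters and the difference was known beforehand. Apart from a composite element with GTTGTTTA, taken up below, no biological explanation was tested. A binding site of the tagged protein remains a hypothesis, since a partner or another protein could place the word there too.

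For tRNA genes, sharing of reads between identical copies may account for part of the excess, since genes with a copy lay near summits more often than unique ones (odds ratio 2.04, 1.22 to 3.32, Fisher exact p = 0.0047). It is argued against for the 143 genes of unique sequence, 14.7% of which (9.81 to 21.4) lay near a summit against 1.45% in shifts, although copies that differ by few bases were not examined. Neighbouring promoters are argued against by the 421 genes over 1 kb from any protein-coding gene start, 23.3% of which lay near a summit. Open chromatin at tRNA and other non-coding genes was not tested, for want of an untagged sample. Random placement was the only comparison, so these summits cannot be credited to the tagged protein.

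ACACTCCG and GTTGTTTA were both present in the 151 bp centred on 44 summits. In 33 pairs they lay on the same strand with starts 23 to 25 bp apart. Of 63 such pairs in the genome 32 lay at a summit, with ACACTCCG within about 50 bp of it, against 11 of 94 other pairs within 100 bp. This window is narrower than the 151 bp, so the 32 and the 33 are different measures. The spacing was read from the same peaks, so the comparison is no independent test. A candidate explanation is a composite element, for which peaks with the pair would be stronger than other peaks with ACACTCCG. Their medians differed by a ratio of 1.07 (0.794 to 1.24, permutation p = 0.779), which does not decide it.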
